A study of Arabidopsis thaliana with 6 samples.

How the data were processed

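RNA was extracted with Trizol and labelled with biotin by a 2-cycle protocol, per the labels' protocols. The files held 1 value per probe set and array for 3 wild-type and 3 35S::CLE41 stem samples. Per the submitters' processing notes RMA and limma were used, with no version or order; the genome build is not given in the sources used here. The deposited values were intensity values on a linear scale, already normalized by the authors per the near-equal medians of the files, although RMA usually ends on the log2 scale; whether they were transformed back is not given in the sources used here. Log2 of each value was taken, a step foreseen for linear values. No background, detection call or scan batch was used here, so probe sets near the background could not be set aside by a measured floor. The size of a difference is therefore uncertain where either genotype's mean lies under 5.67, the cut for the dimmest 40%, as for *PTL*, *CCR2*, *IAA20*, *IAA29*, *GID1B* and *WRKY53*. Normalization to like distributions assumes that as many transcripts rise as fall, so the balance of higher and lower calls depends on it.

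Probe sets were named from a platform annotation table, updated through a RefSeq gene table (TAIR10.1 annotation). Of 22746 probe sets, 13513 mapped to 1 gene, of which 13436 were found in the RefSeq table and 11933 had a locus name only, and 503 mapped to several genes and were not named. The other 8730 were not listed and are unnamed here, not without a gene. The share called was 12.6% among probe sets mapped to 1 gene and 18.5% among those not listed, so the named genes are a narrower view of the differences than the counts over all probe sets. No coordinates are given.

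Each probe set was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, genotype as the factor, two-sided), with Benjamini-Hochberg adjustment over all 22746 probe sets and a threshold of 0.05. The SE of a difference is that of the moderated fit. In such a small design an exact permutation test of 1 probe set cannot go below p = 0.1, so none was run. Gene lists were tested with camera (preset inter-gene correlation 0.01) on 1 probe set per gene, that with the highest mean, with adjustment over the 10 lists that had at least 3 measured genes. Of 24 lists with 518 genes, written from textbook knowledge before the data were examined, 65 genes were measured, and 4 lists had none. Measured here means that the probe table tied a probe set to that gene alone, so other genes may be on the array unnamed. The auxin, lignin and gibberellin calls were lost with an estimated correlation. For lignin that estimate (-0.0758) lay under the preset 0.01, so genes varying together do not account for its loss. The fry test, which asks whether a list's genes move on balance one way, called 6 lists. The groups, the tests, the alternative settings and the rule for named genes were also fixed before the data were examined. The rule took *CLE41* and 6 pathway genes, then the 10 largest rises and falls among called probe sets of 1 gene whose arrays did not overlap, with at most 3 known only by locus per side. From each list it took up to 4 called members, or the 2 with the smallest p where fewer were called. *CLE44*, *GH3.1*, *GH3.3*, *GH3.5*, *GID1A*, *SPCH*, *MUTE* and *XTH19* were named in addition, after their values were seen.

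The procedure was tested on simulated data for 35S::CLE41 against wild type over 22746 probe sets, 200 of them changed. It recovered 18% of changes of 0.5 on the log2 scale, 66% of 1, 98% of 2 and 98% of 4, with 7 false calls. Small differences were thus often missed in the simulation, with 3 arrays per genotype. The simulation gave 147 calls against 3364 in the data, so its cut on unadjusted p was stricter, and no simulated array stood apart. The recovery and the count of false calls therefore do not carry over to the data. With no shift planted 0 of 10 lists were called, and the auxin list was called when a shift of 1 was planted in it. The simulated noise was independent between genes, so this does not test lists whose genes vary together. In the data the estimated correlation was 0.144 for auxin, 0.739 for gibberellin and -0.0758 for lignin.

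Alternatives were the replicate number as a block, arrays shifted to 1 median, quantile normalization again, leaving out the dimmest 40% of probe sets, only probe sets specific to 1 gene, eBayes with trend and robust, array weights, a plain two-sample test in place of the moderated one, other thresholds, limma treat, fry, an estimated correlation, and leaving out each array in turn. The cambium list without *CLE41* was tested in addition, a choice made after seeing the data. Figures were drawn with matplotlib 3.10.9.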

Results

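Transcript levels were measured in inflorescence stems of *Arabidopsis thaliana* ecotype Columbia, comparing wild-type plants with plants that express *CLE41* from the 35S promoter, a viral promoter active in most tissues. *CLE41* encodes a small secreted peptide known as TDIF, which is normally made in the phloem and perceived by the receptor kinase PXY in the vascular cambium, the dividing cell layer between xylem and phloem. The plants were 5 weeks old and had grown under 16 h of light and 8 h of dark. RNA came from the basal part of the stem, without the 1 cm directly above the rosette. Each genotype had 3 samples, each hybridised to 1 array, and each array gave a normalized intensity for 22746 probe sets. Nothing in the labels says that the samples came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Median intensity lay between 91.9 and 101 on the 6 arrays. The probe table used here tied 13513 probe sets to 1 gene and 503 to several genes, and did not list 8730. *PXY*, *WOX4*, *WOX14*, *ATHB8*, *TMO6* and *LBD4* had no named probe set in it and were not analysed here. Below, a gene is called measured where that table tied a probe set to it alone.

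The overexpressed gene itself was measured first. *CLE41* (AT3G24770) had a log2 intensity of 9.69 ± 0.28 (SD, n = 3) in wild type and 11.46 ± 0.24 (SD, n = 3) in 35S::CLE41. This is a log2 difference of 1.77 (SE 0.18), or 3.40-fold, with a limma adjusted p of 0.0013, and each 35S::CLE41 array lay above each wild-type array. *CLE44* (AT4G13195), which encodes the same TDIF peptide, differed by -0.11 (SE 0.16; adjusted p = 0.715).

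The genotypes differed widely. Of 22746 probe sets, 3364 passed an adjusted p of 0.05, 1803 of them higher and 1561 lower in 35S::CLE41. A difference of at least 2-fold was found for 949 of these, 476 higher and 473 lower. Counted by gene, with 1 probe set each, 941 genes rose and 742 fell among 13355 measured. The arrays of the genotypes did not overlap for 34.5% of probe sets, where chance gives 10% for 3 against 3. The balance of higher and lower calls moved with the scaling: with all arrays shifted to 1 median, 1392 probe sets were higher and 1975 lower. The count of calls was 1906, 1699 and 1930 without 35S::CLE41 replicates 1, 2 and 3 in turn.

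Wild-type replicate 2 stood apart from the other wild-type arrays. It differed at least 2-fold from their mean at 365 probe sets, against 32 to 100 for the other 5 arrays compared with their own group in the same way. On the axis from the other wild-type arrays to the 35S::CLE41 arrays it lay at -28.5%, on the far side of wild type. Without it, 2872 probe sets were called, 1490 higher and 1382 lower, and 2620 of them were also called with all arrays.

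**Figure D1:**
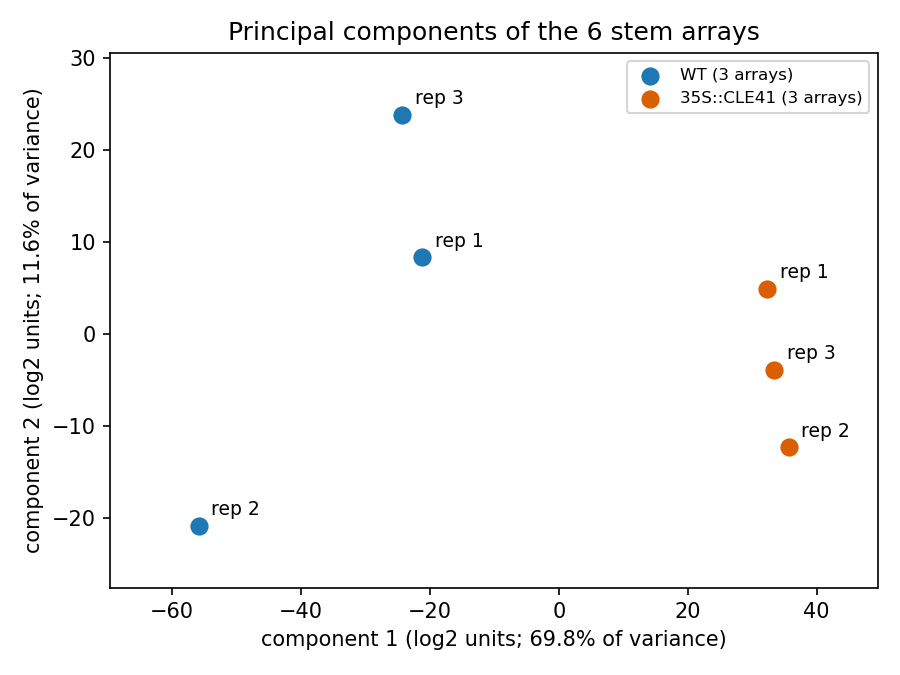
Principal components of log2 intensity over all probe sets, with component 1 (69.8% of variance) on the horizontal axis and component 2 (11.6%) on the vertical axis, both in log2 units. Each point is 1 array: the 3 35S::CLE41 arrays lie between 32.3 and 35.7 on component 1, and the wild-type arrays at -21.2, -55.8 (replicate 2) and -24.3.

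The genes described next had the largest rises and falls with at most 3 known only by locus on each side, so some larger changes of such genes are left out. Sizes and order are uncertain for AT1G65500, AT1G76960, AT1G18980, *IAA30*, *CML41*, *SETH6*, *AR781*, AT2G33850 and AT5G51950, whose lower genotype mean lay under 5.67, the log2 intensity below which the dimmest 40% of probe sets lie. AT1G65500 rose by 4.03 on the log2 scale (SE 0.52), or 16.4-fold; without 35S::CLE41 replicate 3 the rise was 3.42, or 10.7-fold, and the 35S::CLE41 arrays spread from 8.56 to 10.81. The next was AT1G76960, which rose by 3.98 (SE 0.47), or 15.8-fold. AT1G18980 rose by 3.11 (SE 0.32). *CHI* (AT2G43570), which encodes a chitinase, rose by 2.55 (SE 0.38), and *IAA30* (AT3G62100), a member of the Aux/IAA family of auxin response repressors, by 2.48 (SE 0.19), or 5.59-fold. *CML41*, encoding a calmodulin-like protein, rose by 2.16 (SE 0.45), and *HAT2*, encoding an auxin-inducible homeodomain-leucine zipper protein, by 2.12 (SE 0.29). *SETH6*, *AR781* and *CLE41* completed the 10 rises named in this way, with log2 differences of 2.05, 1.90 and 1.77. Like AT1G65500, *CHI* (7.87, 8.23 and 9.17), *CML41* (6.54, 7.36 and 8.58) and *AR781* (7.17, 7.29 and 7.92) climbed from 35S::CLE41 replicate 1 to 3. So did *WRKY53* and AT5G64120, given below, and the sizes of these rises leaned on replicate 3. *HAT2*, *SETH6* and *CLE41* were highest in 35S::CLE41 replicate 2 instead.

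Among the falls AT2G33850 differed by -3.95 (SE 0.32), AT5G51950 by -3.46 (SE 0.33) and AT3G54400 by -3.19 (SE 0.21). *WSD1* (AT5G37300), encoding the wax ester synthase of stem cuticular wax, fell by 3.08 (SE 0.24), or 8.46-fold. *TUB1* (AT1G75780), a beta-tubulin gene, fell by 2.86 (SE 0.17) from a log2 intensity of 10.92 ± 0.28 to 8.06 ± 0.20 (SD, n = 3 each), or 7.26-fold. *XTH16*, encoding a xyloglucan endotransglucosylase/hydrolase that cuts and rejoins wall xyloglucan, fell by 2.59 (SE 0.30). *LUP5*, encoding a triterpene synthase, had a log2 difference of -2.55 and *SBT1.3*, encoding a subtilisin-like protease, one of -2.42. *ARPN*, encoding a plantacyanin, followed at -2.16 and *BZIP61*, encoding a bZIP transcription factor, at -2.12. Adjusted p for these rises and falls ran from 0.000252 for *TUB1* to 0.0181 for *CML41*. Without 35S::CLE41 replicate 2 *CML41* was no longer called (adjusted p = 0.063), and the others were called without each single array. The sizes leaned on wild-type replicate 2, the lowest wild-type array for each of these rises and the highest for each fall. Without that array each difference was smaller in size, such as 3.45 for AT1G76960, 1.745 for *HAT2*, -1.89 for *SBT1.3* and -1.62 for *ARPN*.

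**Figure D2:**
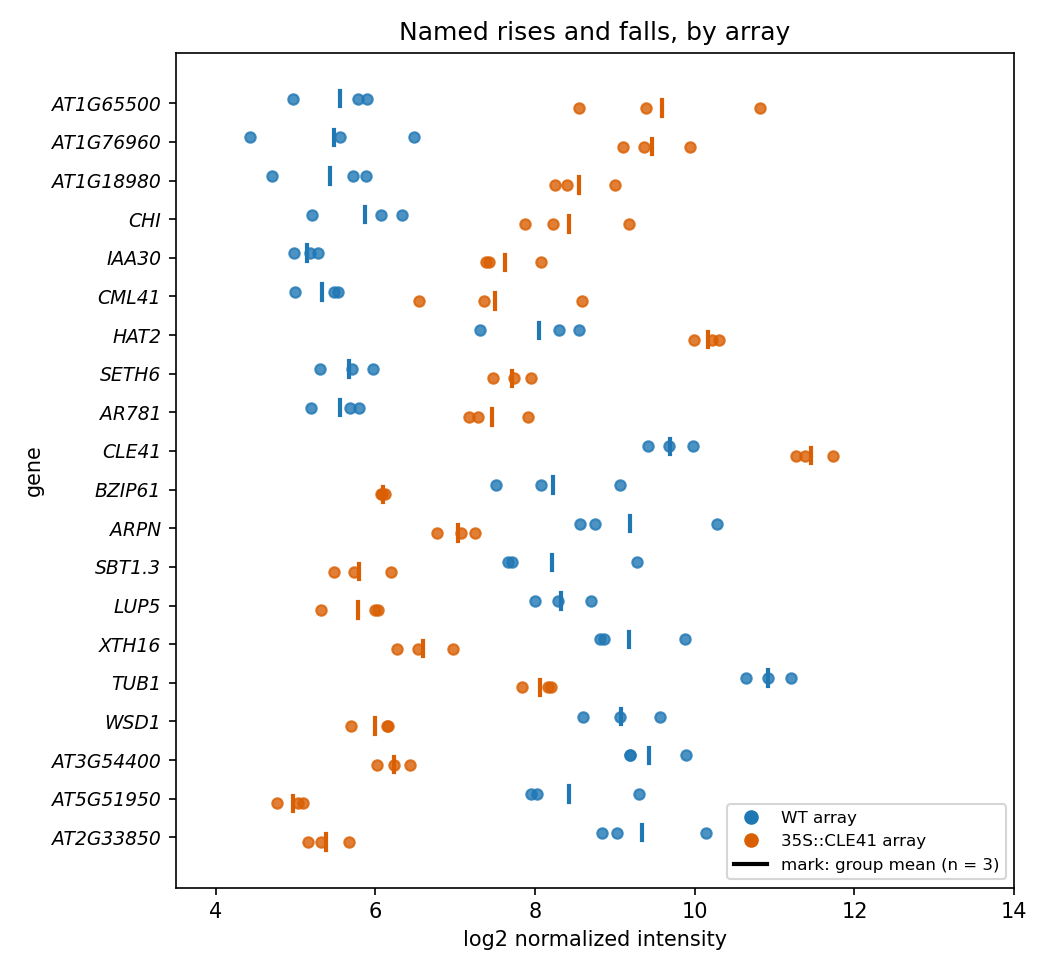
Log2 normalized intensity (horizontal axis) of the 10 named rises and 10 named falls, the largest called with at most 3 genes per side known only by locus (vertical axis), with 1 point per array and a vertical mark at each group mean (n = 3). For *TUB1*, wild-type arrays lie between 10.6 and 11.2 and 35S::CLE41 arrays between 7.84 and 8.20, and for each gene drawn the arrays of the genotypes do not overlap.

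Cambium regulators were examined with a list of 40 genes, of which 8 were measured. The list as a set was not called by camera, limma's competitive gene set test (adjusted p = 0.119). It was called without wild-type replicate 2 (adjusted p = 0.0406), but the list holds *CLE41* itself, whose rise is set by the design. Over the other 7 genes the mean log2 difference was 0.12, against 0.33 with *CLE41*, and that set was called neither with all arrays (adjusted p = 0.297) nor without wild-type replicate 2 (adjusted p = 0.147). Among the 8 measured *CLE41*, *PTL* and *MOL1* rose, none fell, and the same count of 3 rose with adjustment over the list alone. *PTL*, a trihelix transcription factor gene, rose by 0.75 (SE 0.16), and *MOL1*, encoding a receptor-like kinase related to PXY that represses cambium activity, by 0.51 (SE 0.12). Both calls depended on single arrays: *PTL* was not called without 35S::CLE41 replicate 2 (adjusted p = 0.0639), nor *MOL1* without wild-type replicates 1 or 3 or 35S::CLE41 replicates 1 or 2 (adjusted p up to 0.0905).

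Lignin genes were higher as a set, with 7 of 29 measured. *AT5G64120* (PRX71), *HCT* and *CCR2* rose, none fell, and 4 rose with adjustment over the list alone (camera adjusted p = 0.0291; adjusted p = 0.27 with an estimated correlation). *HCT*, encoding an acyltransferase of monolignol synthesis, rose by 1.24 (SE 0.30), *CCR2* (AT1G80820), encoding a cinnamoyl-CoA reductase, by 0.96 (SE 0.17), and the peroxidase gene AT5G64120 by 1.77 (SE 0.41). In wild-type replicate 2 *HCT* differed by -1.13 from the other wild-type arrays. The set lost its call without wild-type replicate 1 (adjusted p = 0.0614), without 35S::CLE41 replicate 3 (adjusted p = 0.0709) and with the dimmest 40% of probe sets left out (adjusted p = 0.0847). *HCT* was not called without wild-type replicate 1 or any single 35S::CLE41 array (adjusted p up to 0.104). AT5G64120 was not called without wild-type replicates 2 or 3 or 35S::CLE41 replicates 2 or 3 (adjusted p up to 0.0979). Array weights and the replicate block (adjusted p = 0.0525) also ended the call of AT5G64120.

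Of the secondary wall list 3 of 29 genes were measured and none was called (camera adjusted p = 0.172; 0 over the list alone). *IRX15* and *IRX10* (GUT2), both needed for xylan, differed by 0.90 (SE 0.39) and 0.45 (SE 0.30). Wild-type replicate 2 was the low array for both, and without it the differences were 0.40 and 0.13. No transcriptional regulator of xylem on the list of 30 had a named probe set. The phloem list had 2 measured genes, *OPS* at 0.41 (SE 0.27) and *SWEET11* at 0.22 (SE 0.19), neither called. Without single arrays *OPS* ran from 0.14 to 0.71 and *SWEET11* from 0.07 to 0.40. The highest *OPS* value, without wild-type replicate 2, was called (adjusted p = 0.0422). Cell division was represented by 3 genes. *MCM7* (PRL), a subunit of the replicative helicase, fell by 0.41 (SE 0.11, adjusted p = 0.0428). It was not called without any single array other than 35S::CLE41 replicate 2 (adjusted p up to 0.145). Its call was also lost with the replicate block (adjusted p = 0.0577) and with eBayes trend and robust settings. The mitotic kinase genes *AUR1* and *AUR2* differed by -0.79 (SE 0.23; adjusted p = 0.0551) and -0.48 (SE 0.21; adjusted p = 0.17), and both were lower with adjustment over the list alone. *AUR1* passed the threshold without wild-type replicates 2 or 3, and in 6 of 7 alternatives that kept all arrays and a moderated test. For *AUR1* and *AUR2* wild-type replicate 2 was 0.84 and 0.78 above the other wild-type arrays, and without it the differences were -0.51 (adjusted p = 0.0336) and -0.22 (adjusted p = 0.25).

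Auxin response genes had the smallest adjusted p among the lists. Of 39 listed genes 7 were measured, and *IAA30*, *IAA29* and *IAA20* rose while none fell. With adjustment over the list alone 6 rose. *IAA29* rose by 1.66 (SE 0.26), or 3.16-fold, and *IAA20* by 1.13 (SE 0.18), or 2.18-fold. The auxin-conjugating enzyme genes *GH3.3* and *GH3.5* differed by 1.16 (SE 0.36) and 0.65 (SE 0.20) without passing over all probe sets. The set was higher by camera (adjusted p = 0.000267; adjusted p = 0.27 with an estimated correlation), with a median log2 difference of 1.13. In wild-type replicate 2 the median of the set was -0.32 relative to the other wild-type arrays.

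Other hormone lists were thinly covered. The 3 gibberellin genes measured were the receptor genes *GID1A*, *GID1B* and *GID1C*. *GID1B* rose by 1.05 (SE 0.16) and *GID1C* by 0.84 (SE 0.16), also over the list alone, and *GID1A* differed by 0.30 (SE 0.15). The set was higher (camera adjusted p = 0.0172; adjusted p = 0.281 with an estimated correlation), while *GID1C* was not called without 35S::CLE41 replicate 2 (adjusted p = 0.0534). In wild-type replicate 2 the median of the set was -0.33 relative to the other wild-type arrays, and without it the mean log2 difference was 0.63 against 0.73. Among cytokinin genes *ARR15*, a type-A response regulator gene that cytokinin induces, rose by 1.16 (SE 0.14; adjusted p = 0.0023), and *ARR16* (RR16) differed by 0.06 (SE 0.11). The brassinosteroid receptor gene *BRL1*, known for its vascular expression, rose by 1.33 (SE 0.22). None of 3 ethylene genes was called (camera adjusted p = 0.953). *EIN3* differed by 0.28 (SE 0.11), from 0.18 to 0.36 without single arrays. *PDF1.2* differed by -1.01 (SE 0.79), from -1.97 without 35S::CLE41 replicate 3 to -0.52 without 35S::CLE41 replicate 2. No jasmonate gene on the list had a named probe set.

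Primary wall genes went both ways. Of 8 measured, *EXPA4* rose by 1.47 (SE 0.22) and *XTH16*, *COB*, *EXPA8* and *XTH19* fell, the same counts of 1 and 4 as over the list alone. *XTH19* was not called without wild-type replicates 1 or 2 or 35S::CLE41 replicates 1 or 2 (adjusted p up to 0.124), nor with the replicate block (adjusted p = 0.0919). *COB*, which orients cellulose deposition, fell by 0.74 (SE 0.11), and the expansin gene *EXPA8* fell by 0.92 (SE 0.18). The set was not called (camera adjusted p = 0.168), but was without wild-type replicate 2 (adjusted p = 0.0498).

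Few of the genes listed for cell types and tissues outside the vasculature were measured. *WSD1*, the fall given above, was the 1 listed epidermal gene with a named probe set. Of 4 stomatal genes none was called over all probe sets and 1, *EPFL9* (STOMAGEN), was lower over the list alone; it differed by -1.06 (SE 0.30; adjusted p = 0.0537) and *FAMA* (FMA) by -0.23 (SE 0.13). Of 6 photosynthesis genes *SBPASE*, encoding a Calvin cycle phosphatase, fell by 0.66 (SE 0.11), also over the list alone, and *PRK* differed by -0.34 (SE 0.13). Neither set was called (camera adjusted p = 0.12 and 0.119), but both were without wild-type replicate 2 (adjusted p = 0.0498 and 0.0406). In that array the set medians were 0.14 and -0.14 relative to the other wild-type arrays. *EPFL9* was highest in it among the wild-type arrays, and without it differed by -0.66 and passed the threshold (adjusted p = 0.00902). It also passed with arrays shifted to 1 median, with eBayes trend and robust settings and with array weights, and *PRK* with array weights. The meristem genes *LAS* and *CLV3* differed by 0.21 (SE 0.18) and -0.17 (SE 0.15), and no listed floral organ identity gene had a named probe set.

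Among early stress genes, listed because handling at harvest can induce them, *WRKY53* and *ZAT10* (STZ), both induced quickly by stress, rose by 1.54 (SE 0.32) and 1.72 (SE 0.37), 2 of 3 genes measured and 2 over the list alone. As a set they were not called (camera adjusted p = 0.12), but were without wild-type replicate 2 (adjusted p = 0.0498), in which *ZAT10* differed by -1.44 from the other wild-type arrays. *WRKY53* was not called without 35S::CLE41 replicate 2, nor *ZAT10* without any single 35S::CLE41 array (adjusted p up to 0.0723 and 0.0734). The clock gene *GI* rose by 0.59 (SE 0.12; adjusted p = 0.015), a call lost without each single 35S::CLE41 array (adjusted p up to 0.0555). *COR15A*, a cold and abscisic acid response gene, differed by -0.96 (SE 0.28, adjusted p = 0.0564), from -1.27 to -0.63 without single arrays. It was the 1 measured gene of the abscisic acid list, so adjustment over the list alone adjusts nothing. It passed the threshold over all probe sets without 35S::CLE41 replicate 1 and with arrays shifted to 1 median. It also passed with the dimmest 40% of probe sets left out and with eBayes trend and robust settings. *SAG101*, of the salicylate list, differed by -0.13 (SE 0.18), and no listed heat shock gene had a named probe set.

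**Figure D3:**
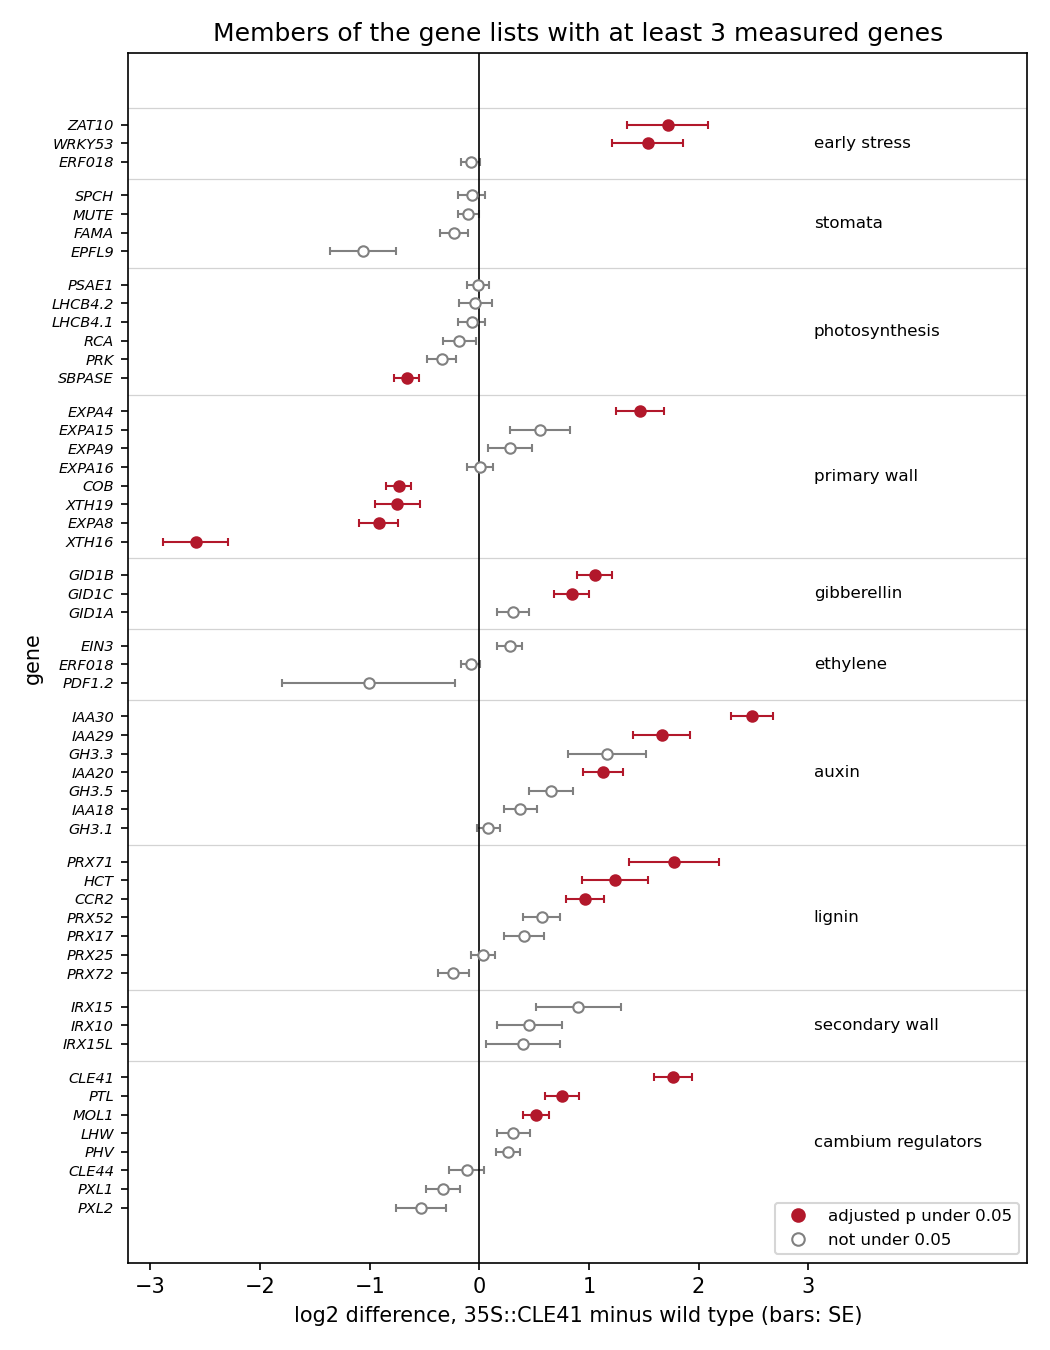
Log2 difference of 35S::CLE41 minus wild type (horizontal axis) for each measured member (vertical axis) of the 10 lists with at least 3 measured genes. Points are estimates from 3 arrays per genotype, bars are SE, and filled points passed an adjusted p of 0.05; *IAA30* lies farthest right at 2.48 and *XTH16* farthest left at -2.59.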

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

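Fits without wild-type replicate 2 were planned for each result, and its use as a doubted array was chosen after seeing the data. Among 54 named genes other than *CLE41*, 661 of 747 alternative values kept their direction and side of the threshold, 66 lost the call, 18 gained it and 2 reversed: *ARR16* (-0.016 with arrays shifted to 1 median) and *SAG101* (0.0084 without wild-type replicate 2; range without single arrays -0.30 to 0.0084). Of 39 named genes called, 29 were called without each array in turn and 3 by the plain test. Deviations of same-numbered samples from their group means were little correlated (-0.01, 0.08 and -0.092). With 3 arrays per genotype this cannot show whether the numbers pair the samples, and the labels do not say. With the replicate block 2897 probe sets were called, 1507 higher and 1390 lower. The block ended the calls of *MCM7* and AT5G64120, gave one to *AUR1* and changed no other call among the lists and the genes named by the rule. Of genes named outside the rule it also ended the calls of *XTH19* (0.0919), *psbA* (0.0576) and AT1G03020 (0.05), and of 11 plastid-encoded falls it ended 6.

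The counts of calls moved by construction with the set tested and the threshold. Probe sets specific to 1 gene gave 1621 calls (896 higher, 725 lower), 460 at least 2-fold (229 and 231). At an adjusted p of 0.01 there were 1125 (503 and 622), and at 0.1 the higher calls numbered 2779. The plain two-sample test, which estimates each spread from few arrays, called 258 (113 and 145), 139 at least 2-fold (48 and 91); under it *CLE41* kept its difference of 1.77 with an adjusted p of 0.0612. Testing against a 2-fold difference (treat) called 59 (20 and 39). Leaving out single arrays gave 1699 to 2872 calls (770 to 1490 higher, 917 to 1382 lower), fewest without 35S::CLE41 arrays (1906, 1699 and 1930), 712 to 1085 at least 2-fold (326 to 578 and 368 to 559), and 1.63 to 1.91 for *CLE41*.

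Among lists, adjusted p without single arrays ran from 3.3e-05 to 0.000853 for auxin, 0.00162 to 0.0398 for gibberellin, 0.00998 to 0.0709 for lignin, 0.0406 to 0.184 for cambium regulators, 0.0406 to 0.381 for photosynthesis, 0.0498 to 0.381 for primary wall, 0.0498 to 0.204 for stomata, 0.0498 to 0.165 for early stress, 0.117 to 0.453 for secondary wall and 0.423 to 0.929 for ethylene. Lignin lost its call with the dimmest 40% left out (0.0847) and, like auxin (both 0.27) and gibberellin (0.281), with an estimated correlation. With *CLE41* left out, a choice made after seeing the data, the cambium list had an adjusted p of 0.297, or 0.147 without wild-type replicate 2, 0.49 with an estimated correlation and 0.101 by fry. Fry called cambium regulators with *CLE41* (0.0218), primary wall (0.0417) and early stress (0.0365). Ethylene, not called in any of these, changed direction with quantile normalization (0.882) and without wild-type replicate 3 (0.834) or 35S::CLE41 replicates 1 (0.929) or 2 (0.864). The cause of these changes was not tested. For lignin the estimated correlation, -0.0758, was under the preset 0.01. Genes varying together thus do not account for the call lignin lost with that estimate. Signal over background was not used here, so how far dim probe sets limit the counts is not known.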

Other observations

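The families and glutaredoxin list below, and the tests of 35S::CLE41 RNA and plastid yield in wild-type replicate 2, were chosen after the data were seen. Among 46 families formed from shared symbol stems with at least 5 measured genes, 5 were called by camera at the preset correlation, and none with an estimated correlation (adjusted p = 0.531 to 0.56). All 5 were also called without wild-type replicate 2 and with arrays shifted to 1 median, in the same direction. Of 9 *XTH* genes, which encode enzymes that remodel wall xyloglucan, 5 fell and none rose (adjusted p = 0.00135; adjusted p = 0.531 with an estimated correlation): *XTH16*, *XTH33* at -1.84 (SE 0.18), *XTH18* at -1.19 (SE 0.18), *XTH32* at -1.14 (SE 0.10) and *XTH19* at -0.75 (SE 0.21). *XTH19* was not called without wild-type replicates 1 or 2 or 35S::CLE41 replicates 1 or 2 (adjusted p up to 0.124), nor with the replicate block (adjusted p = 0.0919). Of 5 beta-tubulin genes *TUB1* fell by 2.86 (SE 0.17) and *TUB5* fell by 1.15 (SE 0.11), while *TUB6* differed by 0.12 (SE 0.13). The camera adjusted p of this set was 0.0164, or 0.531 with an estimated correlation.

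Of 8 autophagy genes with the *ATG* stem 3 rose and none fell (camera adjusted p = 0.00135, or 0.56 with an estimated correlation). Apart from *ATG3*, which differed by 0.23 and was not called, all were *ATG8* genes, so other autophagy genes are not covered. In wild-type replicate 2 the median of the set was -0.31 relative to the other wild-type arrays. The median log2 difference was 0.51 with that array and 0.43 without it. *ATG8F* rose by 0.68 (SE 0.13), *ATG8G* by 0.71 (SE 0.19) and *ATG8D* by 0.56 (SE 0.16); ATG8 proteins coat the autophagosome membrane. These calls depended on single arrays: *ATG8F* lost its call without 35S::CLE41 replicates 2 or 3 (adjusted p up to 0.0544), *ATG8G* without wild-type replicates 1 or 2 or 35S::CLE41 replicates 1 or 3 (up to 0.135), and *ATG8D* without any single array other than wild-type replicate 3 (up to 0.151). Of 69 plastid-encoded probe sets 11 fell, 10 of them losing the call without at least 1 single array and 6 with the replicate block, and 1, *psbA*, rose by 0.39 (SE 0.10; set adjusted p = 0.000463; adjusted p = 0.56 with an estimated correlation). The falls were led by *rpl22* at -1.29 (SE 0.19) and *rps3* at -0.94 (SE 0.19), both ribosomal protein genes. *rpl22* was called without each single array, *rps3* was not without wild-type replicate 1 or 35S::CLE41 replicates 1 or 2 (adjusted p up to 0.0704), and *psbA* was not without any single array (up to 0.113). The median log2 intensity of plastid-encoded probe sets was 10.74, 10.96 and 10.57 in wild-type replicates 1 to 3 and 10.35, 10.20 and 10.40 in 35S::CLE41. The median log2 difference of the 69 probe sets was smaller, -0.19, or -0.16 without wild-type replicate 2. That array was the highest for *rpl22* and *rps3*.

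The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many calls (3364, highest other 0), the 1 with as many at least 2-fold (949, highest other 0) and the 1 with as many lists called (3, highest other 2). Every other split mixes the genotypes, so their difference widens the spread within its groups. The counts of 0 there follow from this and do not measure chance. Some of the other splits called 1 or 2 lists.

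Wild-type replicate 2 differed from the other wild-type arrays at 365 probe sets by at least 2-fold. A curve on intensity carried 0.54% of the variance of its difference, which argued against an intensity-dependent scaling that remained after normalization. Normalization to like distributions removes most of such scaling, so this cannot decide on the array before that step. RNA from 35S::CLE41 was argued against by its position of -28.5% on the genotype axis, on the side away from 35S::CLE41. A different yield of plastid transcripts was argued against as the whole cause by the nuclear probe sets alone. Of the 365, 170 mapped to 1 nuclear gene each (24 and 41 such for the other wild-type arrays). A further 2 were plastid-encoded, 1.16% of these 2 kinds, with 193 not placed. That share decides nothing, since only 69 probe sets in all were known as plastid-encoded, fewer than the 170. It replaced a test on the plastid share of the squared difference (0.426%), set aside as void after its result was seen. What sets the array apart, plastid yield for those 2 included, stays open, and no biological explanation was tested, since the labels give no group for it.

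Of 7 Aux/IAA genes *IAA20*, *IAA29* and *IAA30* rose (family adjusted p = 0.0419; adjusted p = 0.531 with an estimated correlation), and *IAA18* differed by 0.38; *IAA31*, *IAA33* and *IAA34* were not called, which says little because they were, like *IAA20*, among the dimmest 40%. A general rise of early auxin-responsive genes may lie behind the 3 rises, but the test on *SAUR* genes could not decide it. Of 68 such genes, the 3 measured were all among the dimmest 40%, with a camera p of 0.694. This was first read as evidence against a general rise and was set aside as void after its result was seen, because its genes lay near the floor. Wild-type replicate 2 alone was argued against, as 90.9% of the auxin list's mean difference was kept without it.

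CC-type glutaredoxins, small redox proteins found in land plants, were among the large rises: AT4G15660 rose by 2.47 (SE 0.24) and AT3G62950 by 2.36 (SE 0.15), sizes that are uncertain because both were among the dimmest 40%. The members whose values had not been seen were tested as a set, and of 13 measured 6 rose and none fell (camera p = 0.000756; p = 0.0235 with an estimated correlation), which is consistent with a rise of the family, a hypothesis found and tested on the same data; AT1G03020 lost its call without wild-type replicates 1 or 3 or 35S::CLE41 replicates 2 or 3 (adjusted p up to 0.0727), and AT4G15690 without wild-type replicate 1 or 35S::CLE41 replicates 2 or 3 (up to 0.0771). Signal shared between near-identical tandem copies was argued against as the whole cause, since 6 members outside the tandem copies on chromosome 4 were called higher. Most of these genes were dim in wild type, and AT3G62950 neighbours AT3G62960, which rose by 1.68, so shared signal between that pair stays open.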
